A study of Mus musculus with 8 samples.

How the data were processed

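RNA of frozen mouse liver was extracted with Trizol, checked by agarose gel electrophoresis and an Agilent analyser, and sequenced on an Illumina HiSeq X10, per the labels' protocols. Base calling with CASAVA 1.8, the aligners Bowtie and TopHat2 and the genome build GRCm38 are named in the submitters' processing notes. The counting program, the annotation, the use of strand and any filters before deposit are not given in the sources used here. The authors deposited 1 table of estimated counts per gene (expected counts, not normalized), of which 94.2% were whole numbers, for 22183 genes. Every value column belonged to 1 of the 8 samples. Of the gene identifiers, 99.8% were found in GENCODE release M21, an annotation of the same build, which supplied gene coordinates; 21733 were protein-coding there, and Xist had no row in the table used here. Because the use of strand is unknown, counts of overlapping genes (such as Dock6 and Angptl8) and of close paralogs (serum amyloid A, Orm, Gbp, metallothionein, glutathione transferase, Cyp and immunoglobulin genes) are uncertain in how reads were divided.

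Estimated counts were rounded to whole numbers, after which 5954 genes were 0 in all libraries. Genes were filtered by filterByExpr, libraries were scaled by TMM, and knockout was compared with control by edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with no covariate and Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. Standard errors were derived from the fold change and the F statistic. CPM values use the TMM-scaled library size, and per-library log2 values of lists use a prior count of 2. The total of 15998391 to 19474696 counts per library sets the precision: a floor of a few counts corresponds to well under 1 CPM, and low genes such as Saa2 in knockout rest on few counts. The intervals and errors given cover the spread between 4 samples per group.

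Gene lists (37, with 719 symbols, 7 of them absent from the table) were written before the data were examined. Lists with at least 4 tested members (33) were compared by limma's camera (limma 3.58.1, correlation preset at 0.01) on log2 CPM, and again with an estimated correlation and by fry. Mitochondrially encoded and sex chromosome genes were described and not tested, and exocrine pancreas (1 tested member) and adipose (3) had too few members. A list's level in a library is the mean over members of log2 CPM minus that gene's mean over the 8 libraries. Member counts are given over all genes and adjusted over the list alone. Sets from the KEGG and Gene Ontology columns of the deposited table (10 to 300 and 15 to 200 tested genes) were also run through camera.

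The genes named were Stat3; the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 log2 CPM, groups that did not overlap and an established symbol; and up to 4 members with the smallest p of each list. With 4 calls, the genes with the smallest p filled each side to 10 and are given as values only. Applying the same filters on level, overlap and symbol to this filling was an interpretation made after the data were seen. Some genes that the rule names are not reported here. The text names a part of the list members so selected, and this part was chosen with their values in view. Further members named beside a list's count (Hpx, Hp, Fgb, Hamp, Gstm1 and Gzma), and Alb, Scd1, Gemin4 and the genes named for the model with Y-linked reads alone, were chosen after their values were seen.

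Samples of 1 group were compared for duplicates by a chi-square statistic of their counts over genes with at least 10 counts; its median per gene was lowest for knockouts 3 and 4 (1.26, mean 10.7), above that of sampling noise, so each library was counted once. Libraries were classed by Y-linked reads (more than 10 counts of Ddx3y, Eif2s3y, Kdm5d and Uty together). Alternatives fixed in advance were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, robust dispersions, the replicate number as a block, each library left out in turn, and other thresholds. Presence or level of Y-linked reads as a term, Y-positive or Y-low libraries alone, and controls 2 and 3 left out together were added after seeing the data. The procedure was tested on simulated data: in 10 runs of 4 against 4 simulated libraries with 11692 genes, 34.2% of genes changed by 1 on the log2 scale and 87.6% of those changed by 2 were recovered, 72 of 1351 calls were false, a list of 25 genes shifted by −1 was called in 10 runs, and 0 of 300 unchanged lists were called. Genes were drawn independently in these runs, so they do not give the false calls of camera for lists whose members vary together. Nor do they give those of the gene test where libraries of 1 group differ in many genes at once, as with sex-linked transcripts.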

Results

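Messenger RNA of whole mouse liver was sequenced in 8 libraries, 4 from mice with 2 floxed copies of Stat3 (control) and 4 from mice that also carried Alb-Cre (knockout). Stat3 is a transcription factor activated by interleukin-6 family cytokines, and Alb-Cre is a transgene in which the albumin promoter drives Cre recombinase in hepatocytes. Both groups received 20% alcohol by gavage, 15 µL per g of body weight, daily for 2 weeks, so the single contrast of the design is genotype under alcohol, and no unexposed group was analysed here. The deposited table held estimated counts for 22183 genes, and the total per library was 15998391 to 19474696 counts. After low counts were filtered, 11692 genes were tested. The labels number the samples within each genotype without saying that they came from separate animals, so p-values measure only the spread between these samples.

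The targeted gene came first, as a check of the labels. Stat3 (ENSMUSG00000004040, GRCm38 chromosome 11, 100885098 to 100939540) was at 66.7 ± 13.4 CPM in control and 27.6 ± 1.95 CPM in knockout (mean ± SD, n = 4 each). It fell by 1.27 on the log2 scale (SE 0.17, adjusted p = 0.0469, edgeR quasi-likelihood test) and was lower in all 4 knockout libraries than in any control library. Control libraries 1 to 4 held 75.1, 72.9, 46.8 and 72.1 CPM, and knockout libraries 1 to 4 held 27.3, 25.1, 29.7 and 28.4 CPM. An exact two-sided permutation test of the 8 values gave p = 0.0286, the smallest that 70 assignments allow. Gene-level counts do not separate floxed exons from the rest of the gene, and whole liver also holds Stat3 transcripts of cells in which Alb-Cre is not active. The adjusted p passed 0.05 without control 3 (0.00108) or knockout 1 (0.0298) and missed it without control 1 (0.0986), control 2 (0.0564), control 4 (0.131), knockout 2 (0.205), knockout 3 (0.184) or knockout 4 (0.227), with fold changes of −1.20 to −1.41. It also missed 0.05 in limma-voom (−1.25, adjusted p = 0.0670).

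Libraries of each genotype differed in sex-linked transcripts. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together held 5, 1, 1672 and 294 counts in controls 1 to 4, and 2, 728, 934 and 842 counts in knockouts 1 to 4. Y-linked reads were therefore present in 2 of 4 control and 3 of 4 knockout libraries, and the labels give no sex. The first principal component of the 500 most variable genes held 55.0% of their variance, and libraries without Y-linked reads lay at its low end (−26.5, −43.0 and −22.0), with control 4 at −6.71 and the other 4 libraries between 14.8 and 34.5. Control 2 stood apart in composition. Albumin (Alb) took 27.3% of its counts against 7.46 to 13.8% in the other libraries, and Scd1, a fatty acid desaturase, was at 311 CPM there against 7849.6 CPM in control 3. Mitochondrially encoded transcripts took 16.2% ± 3.26 of counts in control and 20.9% ± 1.19 in knockout (SD, n = 4 each).

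**Figure D1:**
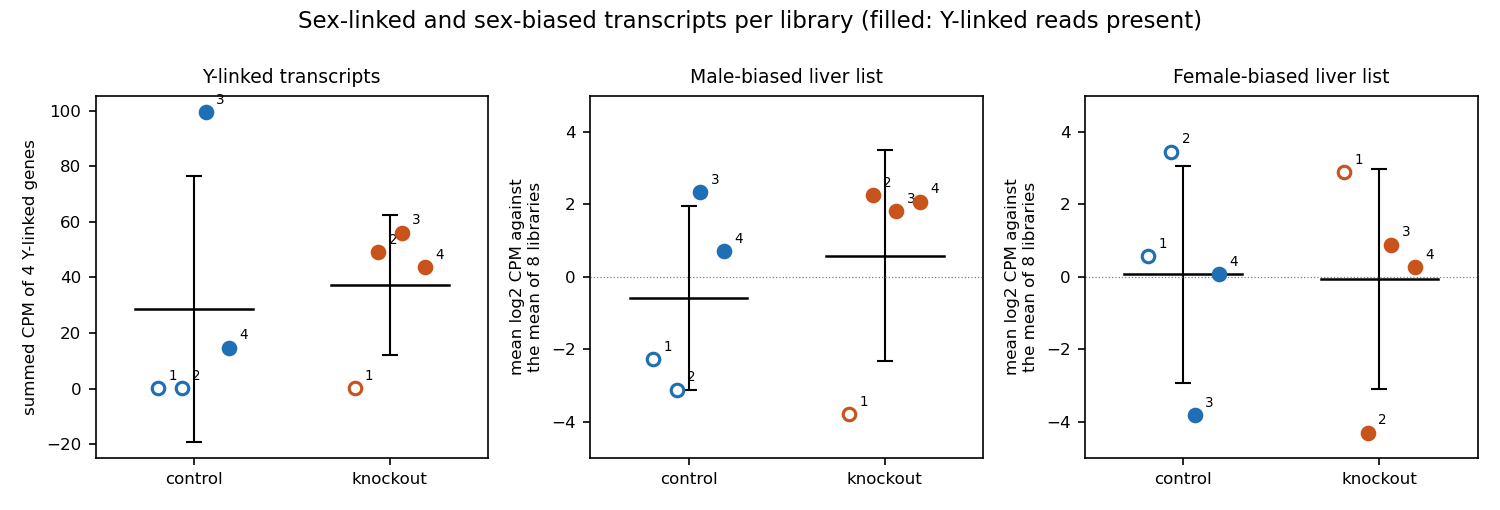
Summed CPM of 4 Y-linked genes (left), and mean log2 CPM of the male-biased and female-biased liver gene lists against the mean of 8 libraries (middle, right), for each library of control and knockout mice. Points are libraries numbered by replicate, filled where Y-linked reads were present, and bars show mean ± SD; control 3 held 99.6 CPM of Y-linked reads and control 4 held 14.7 CPM.

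Across all genes, 4 fell and 0 rose at adjusted p under 0.05 in edgeR's quasi-likelihood test: Saa2, Saa1, Nucb2 and Stat3. Saa1 and Saa2, which encode acute-phase apolipoproteins of the serum amyloid A family, showed the largest falls of the 4. Saa2 (ENSMUSG00000057465, chromosome 7, 46751790 to 46754313) fell by 5.90 on the log2 scale (SE 0.62, adjusted p = 0.0167), from 12.4 ± 7.82 to 0.210 ± 0.118 CPM (n = 4 each). Saa1 (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980) fell by 4.07 (SE 0.54, adjusted p = 0.0469), from 26.1 ± 17.6 to 1.56 ± 0.574 CPM. Nucb2 (ENSMUSG00000030659, chromosome 7, 116504369 to 116540584), which encodes the precursor of nesfatin-1, fell by 2.19 (SE 0.30, adjusted p = 0.0469), from 6.54 ± 0.838 to 1.42 ± 0.572 CPM. Saa1 and Saa2 are close paralogs, so the division of reads between them is uncertain. At an unadjusted p under 0.05 there were 1639 genes (649 higher, 990 lower, 585 expected by chance), and DESeq2 called 269 (111 higher, 158 lower), while limma-voom called 0. In 828 genes (7.08%) the groups did not overlap, against 2.86% by chance. The count was 27 with presence of Y-linked reads as a term in the model, an alternative chosen after seeing the data, and 138 with their level as a term. It was 324 without control 3, 67 without knockout 1, 7 without control 2, 1 without control 1 and 0 without any 1 of the other 4 libraries.

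Below the threshold, the genes with the smallest p among those whose groups did not overlap are given as values. On the lower side they included Mt2, a metallothionein (log2 fold change −4.39, adjusted p = 0.0513), Lcn2, the secreted siderophore-binding protein lipocalin-2 (−4.42, adjusted p = 0.0513), Orm1, an acute-phase glycoprotein (−1.11, adjusted p = 0.0513), Fgl1, a fibrinogen-like hepatocyte protein (−3.35), the receptor gene Egfr (−1.49) and Hc, complement component C5 (−1.10), the last 3 at adjusted p = 0.0583. On the higher side Per2, a clock repressor, had a value of 1.46 (adjusted p = 0.0513). Slc1a4, a neutral amino acid transporter (1.04), Hlf, a rhythmic transcription factor (0.87), Angptl8, an inhibitor of lipoprotein lipase (1.40), Ighm, the IgM heavy chain (4.81), Dock6 (1.27), Aatk (3.93) and Angptl6 (1.03) all had adjusted p = 0.0583. Of these, Lcn2, Mt2, Orm1, Fgl1, Egfr, Hc, Per2, Slc1a4, Hlf and Dock6 passed with presence of Y-linked reads as a term (adjusted p 0.0111 to 0.0407), whereas Angptl8 (adjusted p = 0.0506), Angptl6 (0.0528), Aatk (0.0837) and Ighm (0.0870) did not. Without control 2 the value of Mt2 was −3.39, without knockout 1 that of Fgl1 was −3.96, and without knockout 4 that of Ighm was 3.62.

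**Figure D2:**
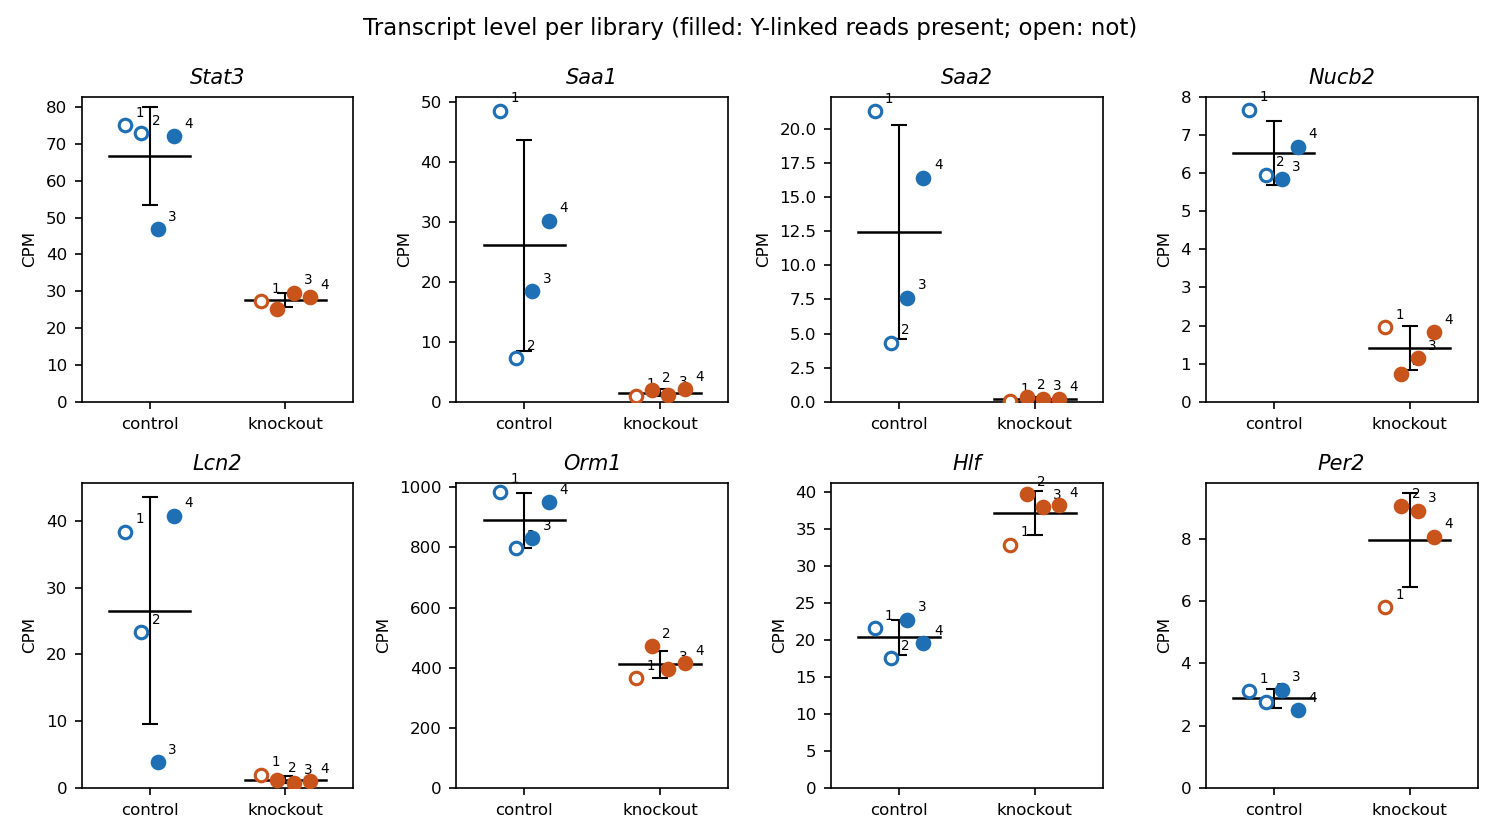
CPM (linear axes from 0) of 8 genes in each library of control and knockout mice. Points are libraries numbered by replicate, filled where Y-linked reads were present, with mean ± SD; Stat3, Saa1, Saa2 and Nucb2 passed the test over all genes and the other 4 had adjusted p of 0.0513 to 0.0583.

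Hepatocyte secretory genes were examined next. Of 24 acute-phase genes tested, 19 fell and 0 rose when adjusted over the list alone (2 fell over all genes, Saa1 and Saa2), and the list's median log2 fold change was −1.06. It was called by camera with a preset correlation (adjusted p = 3.91e-17) but not with an estimated one (adjusted p = 0.189 with an estimated correlation). Abundant plasma proteins were among them: haemopexin (Hpx) went from 4929.0 ± 1115.6 to 2404.9 ± 34.5 CPM, haptoglobin (Hp) from 2881 ± 621 to 1483 ± 31.2 CPM, and the fibrinogen chain Fgb from 4623 ± 1207 to 2295 ± 337 CPM (n = 4 each). Hamp, which encodes the iron regulator hepcidin, went the other way without passing (1.95, SE 0.86, adjusted p over the list alone 0.0523), from 104 ± 81.6 to 402 ± 62.3 CPM with 1.35 CPM in control 2. With presence of Y-linked reads as a term 1 member of the list rose and 20 fell. The mean list level of every knockout library (−0.47 to −0.70 log2 against the mean of 8 libraries) lay below every control library (0.11 to 0.93, lowest in control 3). Of 29 complement and coagulation genes, 6 fell over the list alone (median −0.29, camera adjusted p = 0.000315, adjusted p = 0.189 with an estimated correlation), among them C3, the central complement component (−0.99, SE 0.25), and F11, coagulation factor XI (−0.65, SE 0.20). Of 24 JAK-STAT receptors and feedback genes, 3 fell over the list alone, among them Cish (−1.61) and Socs3 (−1.14), feedback inhibitors induced by STAT proteins. That list had a median of −0.29 and a camera adjusted p of 0.0160 (adjusted p = 0.360 with an estimated correlation). Its call was lost among Y-positive libraries alone (adjusted p = 0.0920).

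Interferon-induced genes and Kupffer cell markers were lower in knockout than in 3 of the 4 control libraries. Of 28 interferon response genes, 24 fell and 0 rose over the list alone, with a median of −1.46 (camera adjusted p = 4.49e-15, adjusted p = 0.360 with an estimated correlation). Irf7, a master regulator of type I interferon, went from 61.4 ± 32.0 to 13.3 ± 1.99 CPM (log2 fold change −2.21, SE 0.41), and Zbp1, a nucleic acid sensor, had a log2 fold change of −2.85 (SE 0.57). Of 21 Kupffer cell and macrophage markers, 13 fell over the list alone (median −1.42, camera adjusted p = 0.000315, adjusted p = 0.558 with an estimated correlation), including the scavenger receptor Marco (−3.36, SE 0.88) and the secreted protein Cd5l (−2.65, SE 0.70). Control 3 stood apart from the other controls. Its interferon level was −0.59, against 0.97 to 1.15 in the other controls and −1.05 to −0.08 in the knockouts. Its Kupffer level was −1.57, below every knockout (−0.76 to −0.35) as well as the other controls (0.74 to 1.43). The Kupffer count was 18 without control 3, 4 without control 2, 5 without control 1, knockout 2 or knockout 3, and 0 among Y-positive libraries alone, where the list was not called (adjusted p = 0.761). Of 14 inflammatory cytokine and adhesion genes, 4 fell over the list alone, among them Cxcl9 (−1.91) and Tlr2 (−1.25), at a median of −0.82 (camera adjusted p = 0.00554, adjusted p = 0.414 with an estimated correlation, and 0.0665 with the preset one in Y-positive libraries alone). Control 3 was at −0.48 against 0.39 to 0.78 in the other controls.

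**Figure D3:**
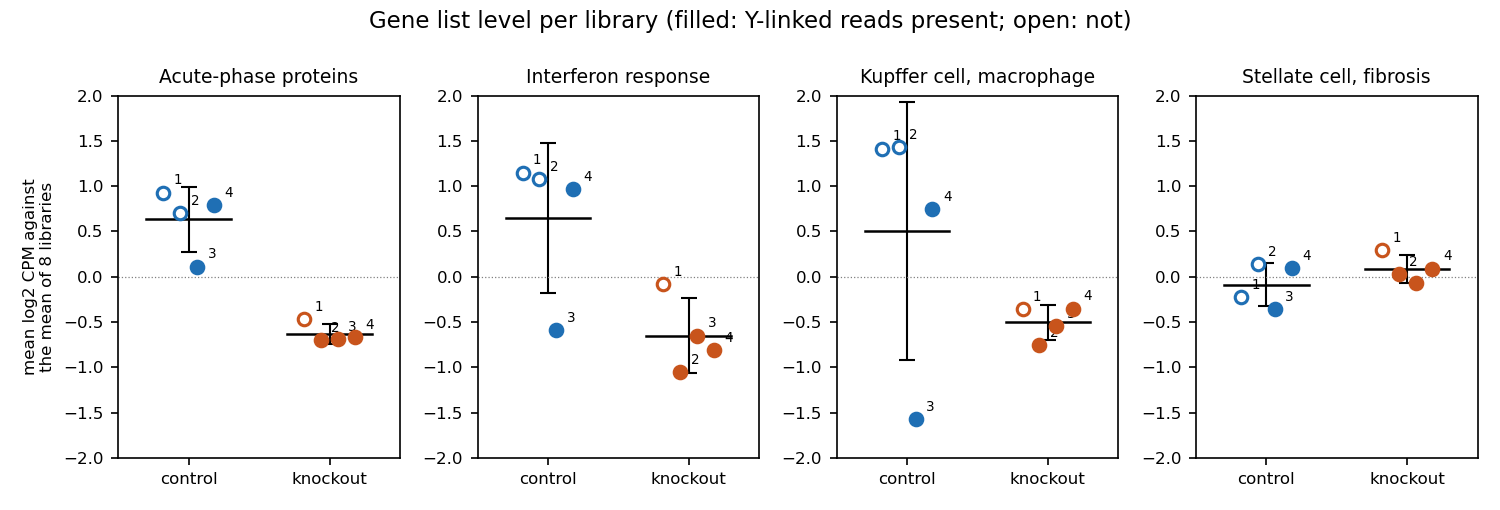
Mean log2 CPM of 4 gene lists against the mean of 8 libraries, for each library of control and knockout mice. Points are libraries numbered by replicate, filled where Y-linked reads were present, with mean ± SD; in the acute-phase panel all 4 knockouts lie below all 4 controls, while control 3 lies at −0.59 in the interferon panel and −1.57 in the Kupffer panel.

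Genes of proliferation and cell death followed with smaller counts. Of 14 cell cycle genes, Cdk1 alone fell over the list alone (−1.87, SE 0.43), and Mki67 had a value of −1.60 (adjusted p over the list alone 0.0527). The list's median was −0.70 (camera adjusted p = 0.00554, adjusted p = 0.360 with an estimated correlation), with −0.16 and no call in Y-positive libraries alone (adjusted p = 0.541). Control 3 was at −0.32 for this list, against 0.25 to 0.63 in the other controls and −0.43 to −0.04 in the knockouts. Of 22 genes of apoptosis and cell survival, 4 fell over the list alone, including the pro-apoptotic Bak1 (−0.85) and the necroptosis effector Mlkl (−1.39), and 1 rose, the stress-induced Gadd45a (1.72). Its median was −0.31 (camera adjusted p = 0.0237, adjusted p = 0.360 with an estimated correlation). Control 2 was at 0.38 against −0.09 to 0.10 in the other controls, and the call was lost without it (adjusted p = 0.108), without controls 2 and 3 (0.199), with a filter of 1 CPM in 4 libraries (0.0524), and in Y-positive libraries alone (0.136).

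Lists of lipid synthesis, lipid droplets, cholesterol and ethanol oxidation were called upward, with 1 of their members past the threshold over the list alone, while fatty acid oxidation was not called. Fatty acid and triglyceride synthesis had a median of 0.28 (camera adjusted p = 0.000127, adjusted p = 0.370 with an estimated correlation) and 0 of 23 members past the threshold over the list alone. Gpam, which starts glycerolipid synthesis, went from 149.6 ± 17.3 to 216 ± 10.7 CPM (0.53, SE 0.15) and Thrsp had a value of 1.41 (SE 0.46), both at an adjusted p over the list alone of 0.0591. Control 2 stood apart in this list at −1.03, with control 3 at −0.37, controls 1 and 4 at 0.10 and 0.03 and the knockouts at 0.11 to 0.43, and without control 2 the list was still called (median 0.33). Cholesterol synthesis and uptake had a median of 0.33 (camera adjusted p = 0.00107, adjusted p = 0.581 with an estimated correlation). Of its 25 members, 1 rose and 0 fell over the list alone, and Mvd, an enzyme of the mevalonate pathway, had a value of 0.91 (SE 0.28, adjusted p over the list alone 0.0651). Control 2 stood apart here too, at −0.75 against −0.09 to 0.08 in the other controls. The list was not called without control 2 (adjusted p = 0.0633) or knockout 1 (0.113), nor without controls 2 and 3 (0.0977), and its median was −0.0935 in Y-positive libraries alone. Lipid droplet and lipoprotein genes had a median of 0.22 (camera adjusted p = 0.0192, adjusted p = 0.479 with an estimated correlation, 0 of 26 members), a call lost without control 1 (adjusted p = 0.123). Ethanol-oxidising enzymes had a median of 0.30 (camera adjusted p = 0.00655, adjusted p = 0.414 with an estimated correlation) and 0 of 13 members past the threshold, Aldh2, which oxidises acetaldehyde, standing at 0.50 (SE 0.20). In Y-positive libraries alone the ethanol list was not called (median 0.07, adjusted p = 0.256).

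Pericentral and clock genes were called upward as lists. Of 15 pericentral hepatocyte genes, Oat, ornithine aminotransferase, rose over the list alone (0.71, SE 0.19), and the list had a median of 0.36 (camera adjusted p = 0.00195, adjusted p = 0.189 with an estimated correlation). The periportal list was not called (median 0.23, adjusted p = 0.0773), although its member Cdh1, E-cadherin, fell over the list alone (−1.06, SE 0.24). Of 17 circadian clock genes, Per2 and Hlf rose over the list alone, and the list had a median of 0.26 (camera adjusted p = 0.0228, adjusted p = 0.360 with an estimated correlation). Its call was lost without control 2 (adjusted p = 0.0858), without controls 2 and 3 (0.199), with a filter of 1 CPM in 4 libraries (0.0524) and with camera on ranks (0.0745), and it was not made in Y-positive libraries alone.

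Markers of other cell types moved in several directions. Of 14 lymphocyte genes, Ighm, Igkc, Jchain and Cd79a, all of the B lineage, rose and Gzma, a granzyme of cytotoxic cells that the naming rule did not select and that was chosen after its values were seen, fell over the list alone. Igkc, the kappa light chain, went from 7.61 ± 3.56 to 63.6 ± 53.9 CPM and Jchain, the joining chain of IgM and IgA, from 5.38 ± 2.99 to 29.2 ± 15.6 CPM (n = 4 each). Without knockout 4 the log2 fold change of Ighm was 3.62 against 4.81, and that of Igkc 2.28 against 3.06. The list's median was 0.36 (camera adjusted p = 0.00554, adjusted p = 0.479 with an estimated correlation). Without control 3 the median was −0.04 with no call (adjusted p = 0.694), as without knockout 1 (median −0.16, adjusted p = 0.0538). Control 3 was at −1.60 for this list, against −0.36 to 0.31 in the other controls. Of 22 stellate cell and fibrosis genes, 6 rose and 0 fell over the list alone, among them the smooth muscle genes Tagln (1.30, SE 0.23) and Acta2 (1.52, SE 0.32) and the retinoid-storage enzyme Lrat (0.65, SE 0.19). The list as a whole was not called (median 0.06, adjusted p = 0.152). Sinusoidal endothelium was called upward (median 0.18, camera adjusted p = 0.0192, adjusted p = 0.633 with an estimated correlation, 0 of 16 members), and not without control 3 (adjusted p = 0.329), control 4 (0.0634) or controls 2 and 3 (0.479).

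Of the other tested lists, none of which camera called, 5 had members past the threshold over the list alone. In glucose metabolism, 1 member rose while Ppargc1a (−1.10), Igfbp1 (−1.43) and Irs2 (−0.86), all induced in fasting, fell (4 of 20 members, list adjusted p = 0.494). Among 26 xenobiotic metabolism genes, 5 rose, including the glutathione transferase Gsta2 (1.84, SE 0.36), and Cyp3a13 fell (−0.94, list adjusted p = 0.185). The metallothioneins Mt2 and Mt1 (−4.39 and −3.45, or −3.39 and −2.26 without control 2) fell and Gsta4 (0.98) and Gstm1 rose among 21 genes of NRF2 and metal stress (list adjusted p = 0.341; its median of 0.09 and its mean against other genes of −0.26 differ in sign). Among 21 genes of endoplasmic reticulum stress and amino acid response, 3 rose, including Manf (0.95) and Trib3 (0.75), and 2 fell, including Psat1 (−2.14, or −1.16 without control 2; list adjusted p = 0.270). In bile acid synthesis and transport, Abcg8, a sterol exporter, fell (−0.60, SE 0.14; list adjusted p = 0.341). Fatty acid oxidation and PPARα targets had 0 of 30 members past the threshold and a median of −0.26 (adjusted p = 0.400) that was 0.14 without control 2, in which Cyp4a14, a PPARα target, was at 10.4 on the log2(CPM + 0.5) scale against a mean of 8.35 in the other controls. In all, 16 of 33 lists were called by camera (8 up, 8 down), 0 with an estimated correlation and 3 by fry's directional test (acute phase, complement and pericentral), and 110 of 610 tested members passed over the list alone against 2 over all genes. The count of 110 was 67 without knockout 2, 62 without knockout 3 and 70 without knockout 4. The count of 2 was 82 without control 3, 18 without knockout 1, 5 without control 2, 1 without control 1 and 0 without any 1 of the other 4 libraries.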

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

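The tests of sex make-up, blood, B-lineage cells and Kupffer cells were chosen after the results were seen; the splits of the samples were planned. The interaction of genotype with Y-linked reads was also chosen after the results were seen. Among 272 tests of 4 libraries of 1 group, 34 found a highest or lowest library whose gap to the nearest other, divided by the range of the group, passed Dixon's 95% critical value, against about 14 expected by chance (1 in 20). Of the genes flagged, Alb, Scd1, Gemin4, Hamp, Gstm1, Parp14 and Serpine2 were chosen after their values were seen. Lists were tested beside their members, so the tests were not independent. The excess of 34 over 14 therefore cannot be read as more outlying libraries than chance gives.

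Knockout 1, a library without Y-linked reads, was set apart most often. Its albumin share was 13.8% against a mean of 8.02% in the other knockouts (gap ratio 0.838). Its list levels stood at −0.47 against −0.69 for acute-phase genes (0.874), −0.30 against −0.11 for complement (0.831), −0.24 against 0.31 for lipid droplets (0.855), −0.22 against 0.12 for endoplasmic reticulum stress (0.963) and −3.78 against 2.04 for male-biased genes (0.927). In log2(CPM + 0.5), knockout 1 stood at 5.76 against 6.89 for Egfr (0.946), 6.68 against 6.19 for Angptl8 (0.844), 4.09 against 5.24 for Bcl3 (0.858), and 8.49 against 8.67 for C4b (0.844). The values were 5.35 against 4.64 for F11 (0.832), 9.30 against 10.5 for Thrsp (0.845), and 2.27 against 5.06 for Fitm1 (0.857). They were 4.90 against 6.10 for Plin5 (0.884), 5.14 against 4.38 for Mpeg1 (0.856) and 6.20 against 6.42 for Ecm1 (0.842). It also stood at 17.0 against 16.3 for Alb (0.886), 2.24 against 4.31 for Serpine2 (0.906) and −1 against 2.58 for Gemin4 (0.989). It was lowest of the knockouts for Gstm1 (gap ratio 0.905) and highest for Parp14 (0.933). The edgeR interaction of genotype with Y-linked reads passed for Gemin4 (fitted log2 difference 10.05, adjusted p = 0.0274), but its Y-low knockout arm is knockout 1 alone, at 0 CPM. It therefore shows that 1 library stands apart and not a difference in the effect of genotype, and the fitted size depends on the prior count.

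Control 3 stood at −0.59 against 1.06 for the interferon list (0.896), and at 5.56 against 6.21 for Stat3 (0.913), 2.28 against 4.99 for Zbp1 (0.854) and 0.28 against 5.76 for Marco (0.863). Control 2 stood at −0.46 against −0.05 for clock genes (0.916), and at 2.92 against 2.40 for Socs3 (0.849), and 6.81 against 9.16 for Thrsp (0.863). The same library stood at 10.4 against 8.35 for Cyp4a14 (0.877), 18.3 against 16.6 for Alb (0.863), 0.89 against 7.04 for Hamp (0.843), 8.28 against 12.9 for Scd1 (0.953) and 8.78 against 1.75 for A1bg, a female-biased gene (0.846). Control 1 stood at 8.90 against 9.84 for Apoc3 (0.864).

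Some libraries held male-biased and female-biased transcripts together. Of genes at least 16-fold apart between the reference libraries, 16 were high in control 3 and 11 in controls 1 and 2. In control 4 the former lay at a median 0.221 of the control 3 level. The latter lay at 0.620 of the level in controls 1 and 2, a sum of 0.841. Y-linked reads were at 0.134 of control 3. These genes were picked by that contrast alone and not for sex bias. The 11 include the Kupffer markers Marco (57.2, 68.9, 0.715 and 39.3 CPM in controls 1 to 4) and Cd5l, and control 3 was low in such markers. By list, control 4 stood at 0.71 for male-biased and 0.08 for female-biased genes, each between control 3 and controls 1 and 2. The Y-linked share of 0.134 (at most 0.174 for any of the 4 genes) argues against a single male with a partly female liver pattern. That share was taken against control 3 alone, at 99.6 CPM. Control 4, at 14.7 CPM, was also below knockouts 2 to 4 (43.8 to 56.2 CPM). Whether RNA of both sexes was mixed, from pooled animals or carry-over, cannot be decided by the sum of 0.841, because Kupffer markers are among the genes behind it. Knockouts 3 and 4 gave sums of 0.852 and 0.937 with Y-linked reads at 1.13 and 0.856 of knockout 2; a mixture (0.852) and single males with some female-type expression (0.856) cannot be told apart there, since Y-linked levels differed by more than that between libraries (99.6 CPM in control 3, 49.2 CPM in knockout 2). No biological explanation beyond the sex of the animals was tested.

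Interferon and Kupffer cell lists were lower in knockout than in controls 1, 2 and 4. Control 3 lay among the knockouts for the interferon list and below all of them for the Kupffer list (−1.57 against −0.76 to −0.35). For interferon the difference in list level was −1.30 (SE 0.46), −1.08 (SE 0.38) with Y status and −1.15 (SE 0.13) with Y level in the model; both stayed below 0 by more than 2 SE, but only the latter kept its bound (−0.90) beyond −0.65, 0.5 of the unadjusted value, so a part played by unequal sex make-up cannot be told apart from genotype. For Kupffer markers it was −1.01 (SE 0.72), −0.73 (SE 0.65) and −0.80 (SE 0.33), and neither bound (0.57 and −0.13) lay beyond 0.5 of the unadjusted value. Whether fewer Kupffer cells were present in knockout livers stays open beside lower expression per cell. Of 11 resident markers, 11 were lower and passed when adjusted over these 11. They were chosen after the fall of the Kupffer list was seen, and that list's members vary together (estimated correlation 0.754). They are therefore no separate evidence. None of the 11 was lower in every knockout than in every control library. The interferon list followed the Kupffer list across 8 libraries (Spearman's rho 0.738, permutation p = 0.0457, and Pearson's r 0.899, permutation p = 0.00605). Without the 2 farthest libraries r was 0.756, and 1 relation was computed. The pair was chosen after both lists were seen to fall, with control 3 low in both. The permutations ran over all 8 libraries regardless of genotype, so their p-values partly restate the shared group difference. Within groups r fell from 0.917 to 0.697 without the 2 farthest, so whether one carries the other stays open.

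Immunoglobulin transcripts were higher in knockout. Residual blood is argued against by the 4 haemoglobin genes, whose median log2 fold change of 0.453 had an upper bound of 0.946 where more than 2 would be needed. Unequal sex make-up as the whole cause is argued against by Ighm, Igkc and Jchain with Y status or Y level in the model, whose lowest value less 2 SE was 1.53, and which passed over all genes with Y level (adjusted p 0.0129 to 0.0261) but neither with Y status (0.0837 to 0.109) nor without a term (0.0583 to 0.0790). More B-lineage cells may account for it: Cd79a, Cd79b and Ms4a1 had a median of 1.14, but of the 3 only Cd79a passed (adjusted p 0.0406 over the 3, against 0.0900 and 0.151). All 3 were low, with means of 0.378 to 0.463 CPM in control and 0.893 to 1.07 CPM in knockout. The groups overlapped for Cd79a, so this hypothesis stays open.

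Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 4 genes of the real split. Chance therefore cannot be excluded for the count of genes. The highest other split, with 263 genes, set controls 1, 2 and 4 with knockout 1 against control 3 with knockouts 2 to 4. It was the division by Y-linked reads but for control 4. It was also the division by genotype but for control 3 and knockout 1, so its genes cannot be assigned to either. For the 16 called lists, 1 of 35 splits, the real one, gave as many (the highest other gave 14). That share is under 0.05, but it is the smallest that 35 splits allow. Camera with its preset correlation called 4 to 14 lists in the other splits, and with an estimated correlation it called 0 in the real one. The test therefore does not exclude chance for the lists called. For the 110 members past the threshold over the list alone, 2 of 35 splits gave as many (the highest other gave 141). Chance cannot be excluded for the count of members.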

How the results depend on the processing

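Alternatives based on Y-linked reads and the one leaving out controls 2 and 3 together were chosen after seeing the data. The Y-low libraries are 2 controls and 1 knockout, whose lone knockout is assumed to vary like the controls, so a call lost there says nothing about stability. Against 4 called genes there were 11 with upper-quartile scaling, 62 with no filter on low counts, 8 with 1 CPM in 4 libraries as the filter, 269 with DESeq2, 0 with limma-voom, 0 with the replicate block, 27 with Y status and 138 with Y level as a term, 125 in Y-positive and 26 in Y-low libraries alone, 187 without controls 2 and 3, and 79 at adjusted p under 0.1 (33 higher, 46 lower). The share of higher calls moved with scaling from 0 of 4 to 4 of 11 with upper-quartile factors, while the median fold change of all genes stayed between −0.03 and −0.01. Leaving out 1 library gave 0 to 324. The labels do not say that the replicate numbers pair the samples. Correlations of deviations between samples of the same number were 0.32, −0.25, 0.09 and 0.18. Of the 4 controls, 2 correlated best with the knockout of their own number. Only the samples numbered 2 differed in presence of Y-linked reads, so these correlations cannot decide whether the samples are paired. With the replicate block the JAK-STAT list was not called (adjusted p = 0.0527).

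Stat3 kept its direction throughout; it was −1.25 with limma-voom (adjusted p = 0.0670) and −1.25 with the replicate block (0.107), −1.43 in Y-low libraries alone (0.363), and −1.41 to −1.20 with 1 library left out (adjusted p 0.00108 to 0.227). Fewer libraries were fitted in the last 2 settings; for limma-voom and the block the cause was not tested.

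Against 16 called lists there were 8 in Y-positive libraries alone, 0 with an estimated correlation, 3 by fry's directional and 8 by its mixed test, and 13 to 18 with 1 library left out. Members past the threshold over all genes (2) numbered 8 with upper-quartile scaling, 18 with no filter, 6 with the 1 CPM filter, 78 with DESeq2, 0 with limma-voom, 0 with the replicate block, 4 with robust dispersion, 10 with Y status, 54 with Y level, 45 in Y-positive and 7 in Y-low libraries, 60 without controls 2 and 3, and 0 to 82 with 1 library left out. Over the list alone (110) they numbered 55 in Y-low libraries and 62 to 161 with 1 left out. The acute-phase count of 19 was 5, and the interferon count of 24 was 6, in Y-low libraries alone, where 1 knockout remained; with 1 library left out they were 19 to 21 and 21 to 27. The Kupffer count of 13 was 0 with limma-voom, 2 with the block, 1 with robust dispersion, 3 with Y status, 0 in Y-positive libraries, and 4 to 18 with 1 left out. The cause was not tested.

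List medians whose test turned direction were, for fatty acid oxidation, 0.14 without control 2 (−0.38 to 0.14 with 1 library left out), 0.10 in Y-positive libraries and 0.34 without controls 2 and 3; for immediate early genes, 0.00388 without control 2 (from −0.25 with 1 library left out), −0.0472 in Y-low libraries and 0.30 without controls 2 and 3; for the female-biased list, 0.69 without control 2 and −0.00275 without knockout 2 (−1.93 to 0.69 with 1 left out), 0.40 with Y status, 0.42 with Y level, 0.30 in Y-positive and 0.15 in Y-low libraries; and for cholangiocytes, −0.00670 without control 2 (−0.16 to 0.22 with 1 left out) and −0.37 in Y-positive libraries. In Y-positive libraries cholesterol synthesis was −0.0935, glucose metabolism 0.0146 and periportal genes 0.0262. In Y-low libraries NRF2 genes were 0.00714, endoplasmic reticulum stress −0.14, heat shock −0.13, the male-biased list −1.24, neutrophils 1.07 and endothelium −0.00612. Lymphocytes were −0.20 without controls 2 and 3. Among 99 named genes and 2071 settings, 2 reversed (Plin5, −0.27 in Y-low libraries, and Gemin4, 0.21 in Y-positive libraries), 24 lost and 321 gained a call; among 790 settings of lists, 24 reversed, 67 lost and 28 gained one. Depth limits low genes such as Saa2 in knockout. Alternatives on a normalized unit were not run, as the table holds counts, nor were list tests under DESeq2.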

Other observations

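The models with Y-linked reads were chosen after the results were seen. Genes of oxidative phosphorylation were called upward in knockout as a set. Among 332 KEGG sets of the deposited annotation, 52 were called by camera and 0 with an estimated correlation. Oxidative phosphorylation was the set with the smallest p (119 genes, median log2 fold change 0.37, adjusted p = 3.56e-13, adjusted p = 0.737 with an estimated correlation), and glutathione metabolism was also called upward (58 genes, median 0.39, adjusted p = 6.04e-07, adjusted p = 0.737 with an estimated correlation). Among 680 Gene Ontology process sets, 36 were called and 0 with an estimated correlation. Complex I assembly was higher (58 genes, median 0.37) and mitochondrial translation was higher (90 genes, median 0.22), while the cellular response to interferon-beta was lower (31 genes, median −1.56), each with an adjusted p of 0.796 to 0.800 with an estimated correlation. The 13 mitochondrially encoded genes, a fixed list that was not tested, took 20.9% ± 1.19 of counts in knockout and 16.2% ± 3.26 in control (SD, n = 4 each), with control 3 at 20.7%.

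The fit with presence of Y-linked reads as a term called 27 genes (12 higher, 15 lower), with all 4 genes of the main test among them. Beyond genes already described it held Fitm1, a lipid droplet gene (2.15), Pltp, phospholipid transfer protein (1.29), Serpine2, a protease inhibitor (2.76), Tsc22d1 (1.34), the interferon-induced Iigp1 (−1.87), Herc6 (−1.56) and Parp14 (−1.17), and Slc37a1 (−2.65), all at adjusted p of 0.0111 to 0.0451 and chosen after their values were seen. The term itself was significant for 33 higher and 7 lower genes in Y-positive libraries. The interaction of genotype with Y-linked reads was called for 1 gene, Gemin4, against 1100 at an unadjusted p under 0.05. Knockout 1 is the only knockout library without Y-linked reads, so the interaction rests on that 1 library and tests no difference between groups of samples. Gemin4 held 0 CPM in knockout 1 and 4.69 to 7.59 CPM in the other 7 libraries and was chosen after its values were seen.

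Male-biased and female-biased lists were not called between the genotypes (adjusted p = 0.145 and 0.774), and their medians were 0.47 and −0.40. Hepatocyte identity (median 0.10, adjusted p = 0.188), erythroid (0.41, 0.0534), heat shock (0.20, 0.0534), autophagy and lysosome (−0.08, 0.224), immediate early (−0.07, 0.835), neutrophil (0.03, 0.204) and cholangiocyte genes (−0.05, 0.407) were not called either. The signs of median, mean and test differed for the immediate early, neutrophil and cholangiocyte lists.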
